A study of Mus musculus with 4 samples.

How the data were processed

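Poly-A RNA from 4 cultures of mouse cortical astrocytes was sequenced. Per the labels' protocols, glial cells were taken from the frontal cortex of CD-1 mice, an outbred strain, at postnatal day 4, and grown in a serum medium with B27 and EGF. They were reseeded at day 6 in vitro at 200000 cells per dish, and RNA was taken 3 days later, after 1 h in Ham's medium without serum. The RNA integrity number was above 9.3, and libraries were made from 500 ng of total RNA with a stranded poly-A kit and 14 cycles of PCR, per the labels' protocols. The labels give no antibody or sorting step, no batch or date, and no statement of how many mice went into a culture or whether the 4 cultures came from separate preparations.

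One deposited table held 45703 genes with their RefSeq coordinates, combined exon length, gene identifier and 4 columns of counts. The submitters' processing notes name bcl2fastq 2.20.0.422, cutadapt 1.17, STAR 2.7.2b, featureCounts 1.6.4 from Subread, and the build GRCm38.p6. Their roles, order and settings are not given in the sources used here. The deposited values are estimated counts, since 31.7% of the values above 0 were not exactly whole numbers (no tolerance, here and wherever genes with whole counts were used), which is what a split of reads between features gives. A gene with split counts may share reads with a paralogue, a pseudogene or an overlapping gene, and the strand setting of the counting is not given in the sources used here. The values of such genes, among them the calmodulin genes and the processed pseudogene Rps2-ps13, are therefore uncertain. All 45703 identifiers were found in a RefSeq table of the same build, and 45701 had the same start and end there. Of 286 calcium gene symbols, 282 were found in the table. Every entry names a gene, so that none was left out of the library sizes.

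CPM (counts per 1e6 counts of the library) were computed here from the deposited counts and the raw library sums, and RPKM as CPM per kilobase of the deposited combined exon length. That length covers all annotated exons of a gene, so that RPKM is too low for a gene whose cells use a short transcript of a long model. A gene was called expressed at a CPM of at least 1 in every library. A total of 3 counts or fewer over the 4 libraries was treated as the floor, under which no level or fold is given. At these library sizes 1 read was 0.0236 to 0.0268 CPM, and 3 counts were 0.0708 to 0.0804 CPM. Counts from PCR-amplified reads without molecular identifiers are not independent molecules, so floors cover counting error only.

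The series has 1 group and no contrast, and its stated aim is a profile of calcium signalling components. The comparisons are therefore between genes within the cultures and between the cultures themselves. Before the data were examined, 17 calcium lists with 54 families, 9 cell type lists and 5 state lists (proliferation, reactive astrocyte, immediate early, ER stress and sex-linked genes) were fixed, along with the tests of the main results, their main settings and most of the other settings. Tests, settings and lists chosen after the data were seen are named as such where they are given. Paralogue levels were compared with edgeR 4.0.16 (quasi-likelihood fit and test, two-sided). Each feature was a pair of genes of 1 family with 8 counts, rounded to whole numbers, the offset was the log of library size times exon length, and the model had terms for the library and the gene. The plan had named the counts as deposited, so the rounding is a departure from it. Pairs entered when at least 1 member was expressed, and p-values were adjusted over all 420 pairs by the Benjamini-Hochberg method at a threshold of 0.05. The SE of a log2 ratio was calculated back from that test, as the absolute log2 ratio over the square root of its F statistic. It is therefore not taken from the SD of the ratio between libraries. A family had a leading member when its top gene was above every other member in that test and in all 4 libraries. The muscarinic receptor family had no expressed member and was not tested. In 10 simulated sets of 420 pairs with a biological coefficient of variation of 0.1, this test called 0.2% of 4000 unchanged pairs, 26% of pairs at 1.25-fold, 90% at 1.5-fold and 100% at 2-fold. The simulated libraries were equally spread and most simulated pairs were unchanged. Neither holds for these data, so the simulated rates do not carry over to them.

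Spread between cultures was the biological coefficient of variation (BCV) of edgeR with TMM normalization, an intercept-only design and its default filter on low counts, which kept 17105 genes. On simulated counts for 17105 genes, the common BCV came out at 0.0495 for a true 0.05 and at 0.199 for a true 0.2. The median BCV of each calcium list was ranked among 10000 random lists of the same size matched on mean expression. Pairs of libraries were compared by a chi-square test over genes with at least 40 counts in the pair, to look for a library deposited more than once. This test sets libraries against counting noise and cannot show that cultures are independent. Each culture was also set against the mean of the other 3 as a log2 ratio with 0.5 CPM added to both. No group of the series shares replicate numbers with another, so no pairing between groups applies, while the pair model compares genes within each library.

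Other settings chosen beforehand were DESeq2 1.42.0 and limma 3.58.1 on the same pairs, no length term, other minimum levels, other normalizations, TPM in place of CPM, the SD of log2 CPM in place of BCV, no library term, and leaving out each culture in turn. Cultures 1 to 3 summed as 1 sample, and the median length of basic protein-coding GENCODE transcripts in place of the combined exon length, were chosen after seeing the data. Calculations used R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

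Genes named in the text were taken by a rule. It covers every member of 9 core families (STIM, ORAI, IP3 receptors, ryanodine receptors, SERCA, PMCA, NCX, the MCU pore and MICU), the 3 most abundant members of every other list, the leading member of every other family, and the 5 expressed calcium genes with the largest BCV. It also covers the 10 most abundant genes of the table and the 10 with the largest BCV at a mean CPM of at least 10. The rule gave 152 genes, 26 of them in core families, and some of these are not reported here. Other genes in the text, such as list members named as low or as exceptions, were chosen after their values were seen, as were the 4 lists of the closing section on X-inactivation escape, hypoxia response, glial transport and GABA-A receptors.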

Results

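The data were 4 RNA-seq libraries, one from each of 4 cultures of cortical astrocytes from early postnatal CD-1 mice, numbered 1 to 4 as in the labels. All belong to 1 group. The libraries held 41084351, 40097076, 37300485 and 42369109 counts for cultures 1 to 4, of which 95.9%, 95.9%, 95.9% and 95.6% fell in protein-coding genes. In total 14725 genes reached a CPM of at least 1 in every library, and 16047 of the 45703 genes had no count in any. Values below are means ± SD over the 4 cultures (n = 4) unless stated otherwise. The series describes the cultures as biological replicates, but the labels do not say which of them came from separate animals or preparations, so the p-values measure only the spread between these 4 libraries. Cultures 1 to 3 differed far less from each other than from culture 4, as described under the spread between cultures, and 3 of the 4 values behind each mean are therefore close to repeats of each other.

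The first question was which calcium signalling components these astrocytes express. Of 282 calcium genes in the table, 189 were expressed in every library. Every one of the 13 genes of mitochondrial calcium uptake was expressed, as were 11 of 12 of store-operated calcium entry, 14 of 15 candidates for calcium leak from the endoplasmic reticulum (ER), and 19 of 21 ER calcium buffers and chaperones. Smaller parts of other lists were expressed, with 16 of 24 glutamate receptors, 12 of 18 voltage-gated calcium channels, 11 of 18 purinergic receptors, 17 of 35 other Gq-type receptors, 12 of 28 TRP and other cation channels and 5 of 14 calcium pumps and their regulators.

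**Figure D1:**
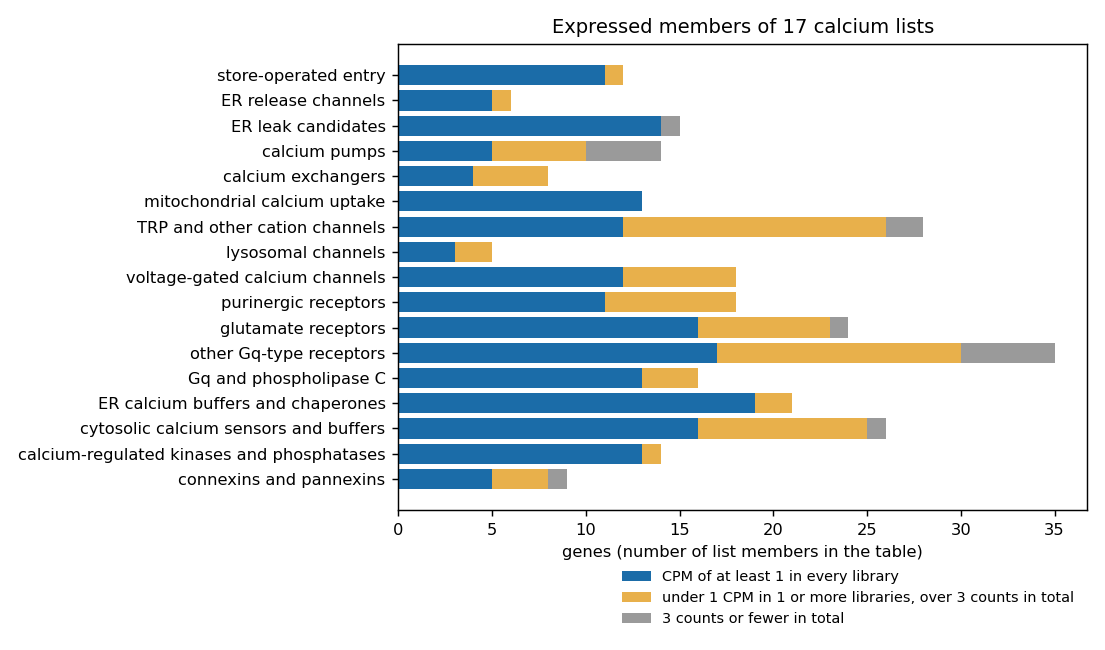
Number of genes in each of 17 calcium lists, split by level in the 4 libraries: CPM of at least 1 in every library, under 1 CPM in at least 1 library, or 3 counts or fewer in total. Mitochondrial calcium uptake had 13 of 13 genes expressed, and calcium pumps 5 of 14.

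The most abundant calcium genes were ER proteins and calmodulins. Calreticulin (Calr), the main calcium-binding protein of the ER lumen, stood at 1039 ± 22.4 CPM and was the 63rd most abundant gene of the table. The ER chaperones Hsp90b1 and Hspa5 (BiP) stood at 947.5 ± 34.0 and 827.8 ± 14.9 CPM, and calumenin (Calu), of the CREC family of low-affinity calcium binders, at 827.1 ± 17.04 CPM. The calmodulin genes Calm3 and Calm2, which encode the same protein, stood at 670.9 ± 16.6 and 381.3 ± 34.3 CPM, with counts that were partly split with other features. Among leak candidates, Tmbim6 (BI-1) had 629.1 ± 23.4 CPM, Ghitm 452.9 ± 20.7 CPM and Sec61a1, the pore of the ER translocon, 264.1 ± 9.02 CPM. This list takes the TMBIM proteins as a whole family, so a place in it does not show that Ghitm acts in the ER. Of the mitochondrial list, the outer membrane channels Vdac1 and Vdac2 had 610.1 ± 13.7 and 272.1 ± 2.58 CPM, and the ATP-magnesium carrier Slc25a23 had 320.0 ± 15.9 CPM.

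Among receptors, the endothelin receptor Ednrb (474.1 ± 23.4 CPM) and the thrombin receptor F2r (452.2 ± 10.1 CPM) were the most abundant of the other Gq-type list, followed by the sphingosine 1-phosphate receptor S1pr1 (157.7 ± 9.56 CPM). The list takes the sphingosine 1-phosphate receptors as a whole family, so a place in it does not show that S1pr1 couples to Gq. Of 24 glutamate receptor genes 16 were expressed, led in CPM by the AMPA receptor subunits Gria2 (304.0 ± 15.5) and Gria3 (125.1 ± 3.03) and the kainate receptor subunit Grik5 (163.8 ± 4.18). The Gq-coupled metabotropic receptor Grm5 had 87.2 ± 4.45 CPM. Of 18 purinergic receptors 11 were expressed, with the adenosine receptor Adora1 at 174.3 ± 25.6 CPM, the ATP and ADP receptor P2ry1 at 29.9 ± 1.19 CPM and P2rx7 at 16.7 ± 1.88 CPM. Downstream, 13 of 16 genes of Gq and phospholipase C were expressed, with Plcb3 at 156.5 ± 4.93, Gnaq at 154.3 ± 5.08 and Plce1 at 127.5 ± 2.05 CPM.

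In the list of TRP and other cation channels, Tmem63b had 138.9 ± 6.89 CPM, the mechanosensitive channel Piezo1 102.4 ± 21.1 CPM and Trpm7 79.0 ± 7.29 CPM. Piezo1 was at 89.4 to 94.8 CPM in cultures 1 to 3 and at 133.8 CPM in culture 4. Trpc1 had 16.3 ± 0.63 CPM and Trpv2 1.75 ± 0.20 CPM, while Trpv4 and Trpa1 were under 1 CPM, at 0.31 ± 0.11 and 0.20 ± 0.17 CPM. Of 18 voltage-gated calcium channel genes 12 were expressed, led by Cacna1a (47.3 ± 2.496 CPM), the pore of P/Q-type channels, the auxiliary subunit Cacna2d1 (43.0 ± 0.41 CPM) and Cacnb3 (38.0 ± 2.27 CPM). Of 5 lysosomal channel genes, Tpcn1 (78.4 ± 5.02 CPM), Mcoln1 (30.5 ± 1.73 CPM) and Tpcn2 (13.6 ± 0.79 CPM) were expressed. Of 9 connexins and pannexins 5 were expressed, of which Gja1 (connexin 43) had 417.5 ± 53.7 CPM, Gjc1 12.2 ± 1.57 CPM and Panx1 10.9 ± 1.29 CPM. Gja1 stood at 431.4 to 457.9 CPM in cultures 1 to 3 and at 338.6 CPM in culture 4.

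Of 14 calcium-regulated kinases and phosphatases 13 were expressed, with Camk2d at 152.1 ± 5.61 CPM and the calcineurin subunits Ppp3ca and Ppp3cb at 133.4 ± 11.9 and 106.4 ± 4.74 CPM. Of 26 cytosolic calcium sensors and buffers 16 were expressed. They did not include the calcium buffers Calb1, Calb2 and Pvalb, at 0.17 ± 0.06, 1.01 ± 0.24 and 0.69 ± 0.17 CPM. Of 8 calcium exchangers 4 were expressed. With TPM in place of CPM the count of expressed calcium genes was 169, and with cultures 1 to 3 summed as 1 sample, a setting chosen after seeing the data, it was 191.

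The second question was which member of each protein family prevails, compared as RPKM ratios within each library. In the core families of store-operated entry, Stim1, the ER calcium sensor, was 1.57-fold above Stim2. The plasma membrane channels Orai1 and Orai3 were not told apart, at a ratio of 1.02, and both were above Orai2. The IP3 receptor Itpr1 was 1.53-fold above Itpr2 (1.23-fold without the length term, 1.26-fold with GENCODE lengths) and 9.61-fold above Itpr3. The ER pump Atp2a2 (SERCA2) was alone at a high level, the plasma membrane pump Atp2b4 was 1.57-fold above Atp2b1, and the mitochondrial uniporter Mcu was 18.9-fold above its dominant-negative paralogue Mcub (54.9-fold without the length term, 32.3-fold with GENCODE lengths).

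**Figure D2:**
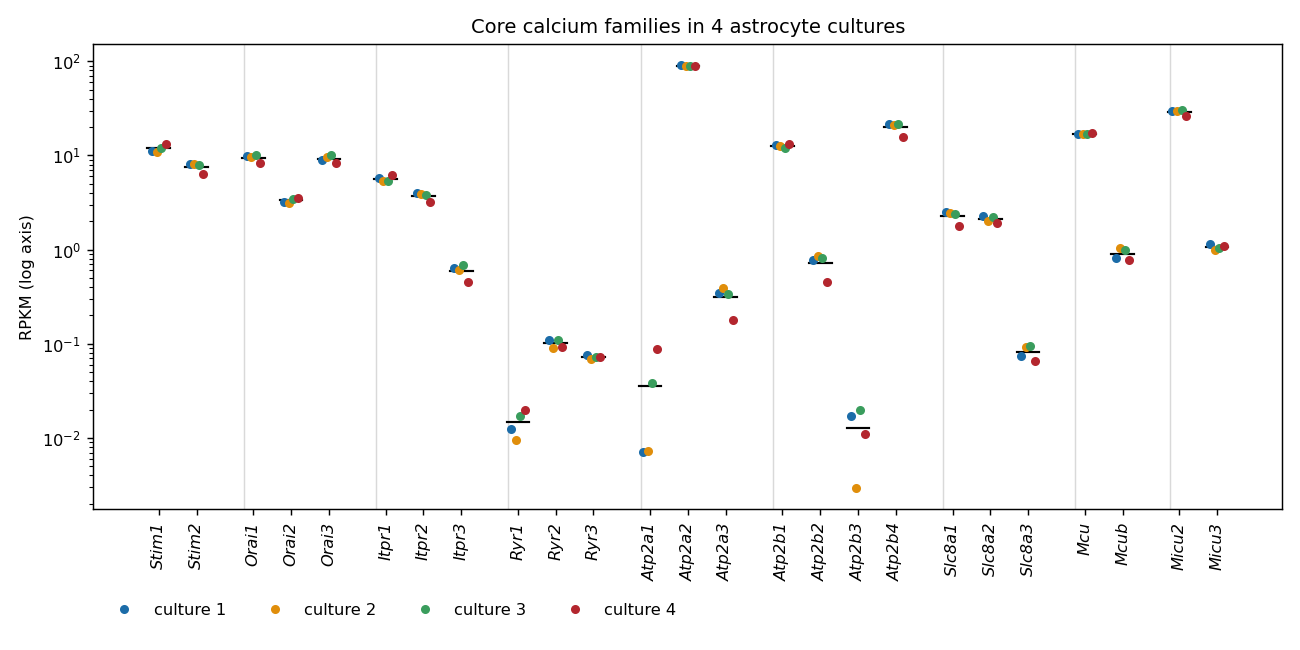
RPKM on a log axis of genes of the core calcium families, with 1 point per culture and a black line at the mean of the 4. Atp2a2 stood high, at a mean of 89.7 RPKM, and the ryanodine receptor genes Ryr1, Ryr2 and Ryr3 at or under a mean of 0.101 RPKM.

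Stim1 (GeneID 20866; GRCm38.p6 chromosome 7, 102261514 to 102437319, plus strand) had 61.2 ± 5.31 CPM or 11.9 ± 1.03 RPKM, and Stim2 (GeneID 116873; chromosome 5, 53998523 to 54121057, plus strand) had 37.4 ± 4.07 CPM or 7.58 ± 0.82 RPKM. Their log2 ratio was 0.65 ± 0.12 (SE; higher in 4 of 4 libraries; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00174). Stim1 was 1.43-fold above Stim2 without culture 4 and 1.72-fold with cultures 1 to 3 summed as 1 sample. This fold was 1.64 without the length term and 1.97 with GENCODE lengths. Orai1 (GeneID 109305; chromosome 5, 123015074 to 123030452, plus strand) had 23.2 ± 1.90 CPM or 9.45 ± 0.77 RPKM and Orai3 (GeneID 269999; chromosome 7, 127769815 to 127775150, plus strand) had 18.4 ± 1.58 CPM or 9.23 ± 0.79 RPKM. The log2 ratio of Orai1 to Orai3 was 0.03 ± 0.08 (SE; edgeR, adjusted p = 0.703). It was 0.33 without the length term (edgeR, adjusted p = 0.00777) and 0.58 with GENCODE transcript lengths (edgeR, adjusted p = 0.000452), so that whether Orai1 led depended on the length used. Orai2 (14.9 ± 0.88 CPM, 3.34 ± 0.20 RPKM) was 2.83-fold below Orai1 (edgeR, adjusted p = 9.62e-06), and 1.55-fold without the length term (edgeR, adjusted p = 0.000956) and 3.65-fold with GENCODE lengths (edgeR, adjusted p = 3.2e-06). Other genes of the list were Saraf, the inhibitor of store-operated entry, at 185.3 ± 14.0 CPM, Asph at 168.7 ± 10.9 CPM and Esyt2 at 71.1 ± 3.36 CPM. The only member below the minimum was Cracr2a, at 0.74 ± 0.13 CPM.

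Itpr1 (GeneID 16438; chromosome 6, 108213083 to 108551116, plus strand) had 58.3 ± 4.35 CPM, Itpr2 47.4 ± 4.49 CPM and Itpr3 5.57 ± 0.94 CPM. The log2 ratio of Itpr1 to Itpr2 was 0.61 ± 0.11 (SE; higher in 4 of 4 libraries; edgeR, adjusted p = 0.0013). It lay between 0.45 and 0.53 in cultures 1 to 3 and at 0.97 in culture 4. Ryanodine receptor transcripts were close to the minimum, with Ryr2 at 1.71 ± 0.17 CPM (275 counts in total), Ryr3 at 1.168 ± 0.04 CPM (188 counts) and Ryr1 at 0.23 ± 0.07 CPM (37.3 counts). Ryr2 was 1.39-fold above Ryr3 (edgeR, adjusted p = 0.0202), a call that was lost without culture 1, 2 or 3 (edgeR, adjusted p = 0.0745, 0.0557 and 0.0686) and with cultures 1 to 3 summed (edgeR, adjusted p = 0.279).

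Atp2a2 (GeneID 11938) had 513.6 ± 6.25 CPM, against 1.45 ± 0.43 CPM for Atp2a3 and 0.12 ± 0.13 CPM for Atp2a1. The log2 ratio of Atp2a2 to Atp2a3 was 8.18 ± 0.19 (SE; edgeR, adjusted p = 3.75e-08). The SERCA regulators phospholamban (Pln) and sarcolipin (Sln) had 2 counts and 1 count in all. Of the plasma membrane pumps, Atp2b4 had 184.6 ± 26.8 CPM, Atp2b1 98.0 ± 3.48 CPM, Atp2b2 9.26 ± 2.33 CPM and Atp2b3 0.11 ± 0.06 CPM. Atp2b4 was above Atp2b1 in 4 of 4 libraries (edgeR, adjusted p = 0.000861), by a log2 ratio of 0.75 to 0.85 in cultures 1 to 3 and of 0.26 in culture 4. Atp2c1, the Golgi pump SPCA1, had 103.1 ± 5.11 CPM. In the sodium-calcium exchangers, Slc8a1 (45.1 ± 6.75 CPM, 2.27 RPKM) and Slc8a2 (16.1 ± 1.22 CPM, 2.11 RPKM) had a ratio of 1.07 (edgeR, adjusted p = 0.362), which became 2.79 without the length term (edgeR, adjusted p = 5.65e-06) and 4.13 with GENCODE lengths (edgeR, adjusted p = 1.18e-06). Without culture 4 the ratio was 1.12 (edgeR, adjusted p = 0.000232), where the p-value measures only the spread between cultures 1 to 3, which were close to repeats. With cultures 1 to 3 summed as 1 sample the ratio was 1.02, and no lead was called. Slc8a3 had 1.06 ± 0.18 CPM. Slc24a3 led the potassium-dependent exchangers at 6.89 ± 0.70 CPM.

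Mcu (GeneID 215999) had 65.3 ± 0.75 CPM and Mcub 1.19 ± 0.18 CPM, a log2 ratio of 4.24 ± 0.12 (SE; edgeR, adjusted p = 1.02e-07). Of the regulators of the uniporter, Micu2 had 67.9 ± 4.46 CPM and Micu3 6.76 ± 0.44 CPM.

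Across all families, 396 of 420 pairs differed (edgeR, Benjamini-Hochberg adjusted over the 420 pairs), and 48 of 53 families had a leading member. The 5 without one were ORAI, the sodium-calcium exchangers, the AMPA receptor subunits (Gria3 and Gria2, ratio 1.03), calmodulin (Calm2 and Calm3, ratio 1.03) and calcineurin A (Ppp3ca and Ppp3cb, ratio 1.08). These pairs too depended on the setting. The log2 ratio of Ppp3ca to Ppp3cb was 0.32 without the length term (edgeR, adjusted p = 0.00466), 0.20 with GENCODE lengths (edgeR, adjusted p = 0.0389) and 0.18 without culture 4 (edgeR, adjusted p = 5.34e-10). The last p-value measures only the spread between cultures 1 to 3, which were close to repeats of each other. With these summed as 1 sample, Ppp3ca was 1.02-fold above Ppp3cb and no lead was called. Calm2 was 1.27-fold above Calm3 with GENCODE lengths (edgeR, adjusted p = 0.00128) and below it without the length term, by a log2 ratio of -0.82 (edgeR, adjusted p = 1.48e-05). Gria2 was 2.43-fold above Gria3 without the length term (edgeR, adjusted p = 4.47e-07). Among the larger folds, several of which moved with the length used, Piezo1 was 71.7-fold above Piezo2, Ednrb 61.0-fold above Ednra, Bdkrb2, the constitutive bradykinin receptor, 43.6-fold above Bdkrb1, Gja1 37.1-fold above Gjc1, Panx1 33.7-fold above Panx2, Plcb3 22.4-fold above Plcb1, Grik5 18.8-fold above Grik3, Sec61a1 16.3-fold above Sec61a2 and F2r 15.6-fold above F2rl1. Intermediate leads were those of Adora1 over Adora2b (12.5-fold), Tpcn1 over Tpcn2 (11.2-fold), Plcg1 over Plcg2 (9.45-fold), Trpm7 over Trpm4 (8.75-fold), Camkk2 over Camkk1 (8.71-fold), Grin3a over Grin2c (7.65-fold), Cacna2d1 over Cacna2d3 (5.73-fold), Trpv2 over Trpv4 (5.40-fold), Grm5 over Grm3 (5.03-fold) and S100a11 over S100a16 (4.07-fold). Leads of under 4-fold included Tmem63b (3.98-fold), Calr over Canx (3.17-fold), P2ry1 over P2ry2 (2.95-fold), S1pr1 over S1pr3 (2.60-fold), Calu over Rcn2 (2.47-fold), Cacnb3 over Cacnb1 (2.36-fold), Plcd4 over Plcd1 (2.25-fold), Adra1d over Adra1b (2.18-fold), Cacna1a over Cacna1h (1.82-fold), Tmbim6 over Ghitm (1.64-fold) and Vdac1 over Vdac2 (1.56-fold).

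Some leads depended on gene length. Camk2g over Camk2d (1.43-fold) changed direction without the length term and with GENCODE lengths. P2rx4 over P2rx7 (1.75-fold) changed direction without the length term, and with GENCODE lengths these genes were not told apart (log2 ratio -0.13, edgeR adjusted p = 0.214). Gna11 over Gnaq (1.64-fold) and Nfatc3 over Nfat5 (1.87-fold) changed direction without the length term only. Lpar6 over Lpar4 (1.72-fold) was lost without the length term (log2 ratio 0.0069; edgeR, adjusted p = 0.952) and changed direction with GENCODE lengths, and Lpar1 was then the top member of the family in both settings. Other folds kept their direction but moved by more than 1.5 times. Without the length term and with GENCODE lengths they were 6.88 and 4.58 for Sec61a1, 16.5 and 8.21 for Panx1, 5.75 and 3.65 for Tpcn1, 7.81 and 12.9 for Plcb3, 135 and 47.2 for Bdkrb2, 22.4 and 53.5 for Grik5, 39.4 and 15.9 for Adora1, 12.7 and 8.59 for Grm5, 14.4 and 8.54 for Cacna2d1, 17.1 and 21.3 for Camkk2, 1.27 and 2.25 for S100a11, 1.44 and 2.65 for Calr, 1.39 and 4.24 for Tmbim6, 34.2 and 20.9 for Gja1, 6.49 and 3.99 for Grin3a, and 14 and 7.85 for Trpm7, each over the same paralogue as above. With cultures 1 to 3 summed as 1 sample, 383 of 422 pairs and 46 families passed, and the lead of Ryr2 over Ryr3 was lost. P2rx4 over P2rx7 still passed the threshold, but P2rx4 no longer led every other member of its family. It was 1.67-fold above the next member in that setting (edgeR, adjusted p = 0.0564).

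The third question was how alike the 4 cultures were. Of the cell type and state lists, culture 4 differed from the mean of the other 3 most in sex-linked genes and in the fibroblast, endothelial, reactive astrocyte, immediate early, microglial, mural and proliferation lists, with median log2 deviations of -1.15 for fibroblasts, -1.0 for the 2 endothelial genes with a mean CPM of at least 1, -0.83, -0.53, -0.52, -0.42 and 0.41 for the others in this order. No enrichment was tested. Against the mean of the other 3 cultures, 34 of 12361 genes were more than 2-fold higher in culture 4 and 111 more than 2-fold lower, while cultures 1, 2 and 3 had 0 higher and 9, 7 and 7 lower. Culture 4 is part of the mean set against cultures 1, 2 and 3, so their counts reflect it as well. All 10 proliferation genes were higher in culture 4, with Top2a at 663.3 CPM against 488.6 to 502.6 CPM and Mki67 at 405.6 against 292.1 to 304.4 CPM. All 12 genes of the reactive astrocyte list were lower, with Serpina3n at 43.7 CPM against 121.7 to 125.9 CPM and Cd44 at 216.1 against 306.1 to 314.9 CPM. The collagen gene Col1a1 was at 72.4 CPM in culture 4 and at 570.1 to 622.6 CPM in the others. These are values of single libraries, with no test of culture 4 against the rest.

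**Figure D3:**
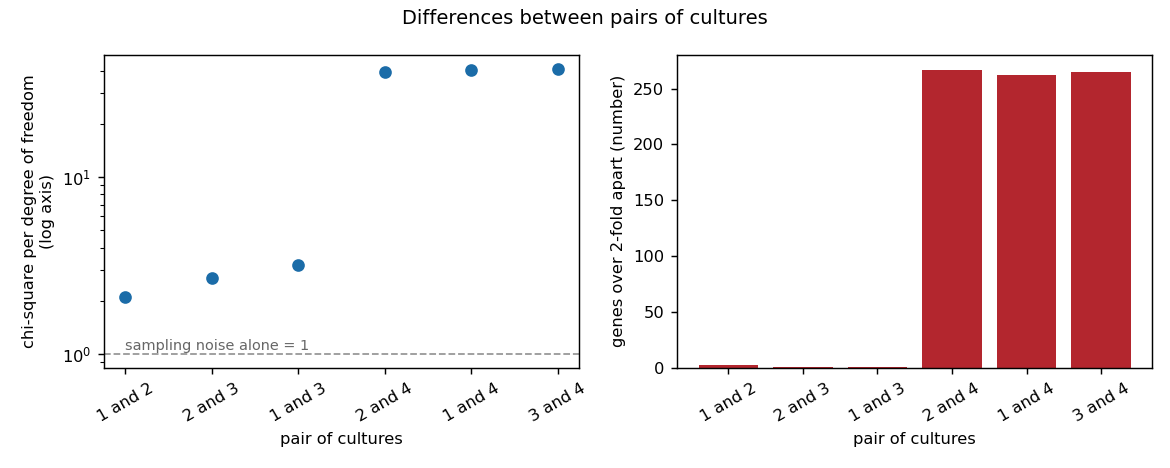
Chi-square per degree of freedom on a log axis (left; 1 is sampling noise alone) and number of genes more than 2-fold apart (right) for the 6 pairs of cultures. The 3 pairs without culture 4 lie at 2.11 to 3.17 and the 3 pairs with it at 39.4 to 41.1.

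The chi-square per degree of freedom was 2.11, 3.17 and 2.68 for the pairs of cultures 1 and 2, 1 and 3, and 2 and 3, and 40.4, 39.4 and 41.1 for cultures 1, 2 and 3 with culture 4. Counting noise alone gives 1, which separate libraries of the same RNA would also exceed, so these values do not show whether cultures 1 to 3 are independent, and n = 4 follows the labels. More than 2-fold apart were 3, 1 and 1 genes in the first 3 pairs and 262, 267 and 265 in the pairs with culture 4. The sex-linked genes split the same way. Xist, the transcript that coats the inactive X chromosome, had 732.1 CPM in culture 4 and 0.146, 0.150 and 0.148 CPM in cultures 1, 2 and 3, while the Y-linked genes Ddx3y and Eif2s3y had 67.5 to 76.4 and 80.3 to 83.5 CPM in cultures 1 to 3 and 0.0944 and 0.0708 CPM in culture 4.

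The common BCV of the 4 cultures was 10.7% over 17105 genes, and 2.62% over cultures 1 to 3 alone. The first principal component of the libraries held 78.1% of the variance. Among genes with a mean CPM of at least 10, the largest BCV values belonged to Rps2-ps13 (92.1%), Eef1a2 (81.5%), Nnat (64.6%), Slc16a3 (60.1%), Col1a1 (59.4%), Ucp2 (57.9%), Gm5611 (53.1%), Col6a2 (51.6%) and Gpr37l1 (50.5%). Genes near 0 in 1 or more libraries, such as Xist, Eif2s3y and Ddx3y, were removed by the filter and have no BCV. This ranking therefore leaves out genes that were near 0 in culture 4 alone. Among expressed calcium genes the largest were Adora2b (45.9%), Gjb6 (33.5%), Nfatc4 (33.2%), Adora2a (33.1%) and S100a6 (28.2%). In core families the BCV was 7.9% for Stim1, 10.8% for Stim2, 9.43% for Orai1, 7.34% for Itpr1, 6.15% for Atp2a2, 12.97% for Atp2b4, 13.4% for Slc8a1 and 5.65% for Mcu. The largest in these families were 25.2% for Atp2a3, 22% for Atp2b2 and 16.4% for Itpr3.

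The median BCV of the 189 calcium genes lay at the 99.8th percentile of 10000 random lists of the same size and expression, at 61.8 over cultures 1 to 3 alone. By list, glutamate receptors lay at the 99.9th percentile, other Gq-type receptors at 99.7, cytosolic sensors and buffers at 99.5, TRP and other cation channels at 96.4, kinases and phosphatases at 95, purinergic receptors at 94.3, exchangers at 90.1, store-operated entry at 83.2, voltage-gated channels at 81.6 and connexins and pannexins at 63.7. ER leak candidates lay at 54.3, lysosomal channels at 48.7, pumps at 46.5, Gq and phospholipase C at 37.7, mitochondrial uptake at 16.3, ER release channels at 4.71 and ER buffers and chaperones at 0.27. Over cultures 1 to 3 alone other Gq-type receptors lay at 96.4, glutamate receptors at 96.2, store-operated entry at 95.3, TRP and other cation channels at 89.9, lysosomal channels at 86.4, kinases and phosphatases at 73.8, voltage-gated channels at 66.6, exchangers at 49.8, pumps at 49.7, ER leak candidates at 39.6, ER release channels at 31, ER buffers and chaperones at 25.9, connexins and pannexins at 24.8, purinergic receptors at 11.2, cytosolic sensors at 8.81, Gq and phospholipase C at 7.21 and mitochondrial uptake at 1.11. With the SD of log2 CPM in place of BCV, ER release channels lay at 66.8 and ER buffers and chaperones at 0.93, and without culture 1, 2 or 3 the ER release channels lay at 21.3, 26.8 and 27.5, so the low rank of the release channels did not hold. These percentiles describe these libraries and are not tests.

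The last question was which cells the cultures held, read from marker lists. Astrocyte markers were the most abundant list, and all 15 were expressed, among them the glutamate transporter Slc1a3 (2601 ± 78.6 CPM), glutamine synthetase (Glul, 1577 ± 81.4 CPM) and Gfap (1339 ± 373 CPM). Genes of neural progenitors and radial glia were also high, with vimentin (Vim) at 5586 ± 581 CPM, Fabp7 at 3808 ± 129 CPM and nestin (Nes) at 983.3 ± 29.3 CPM. Microglial transcripts were present at a far lower level, and most endothelial markers were under 1 CPM. No cell share is inferred from these levels.

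**Figure D4:**
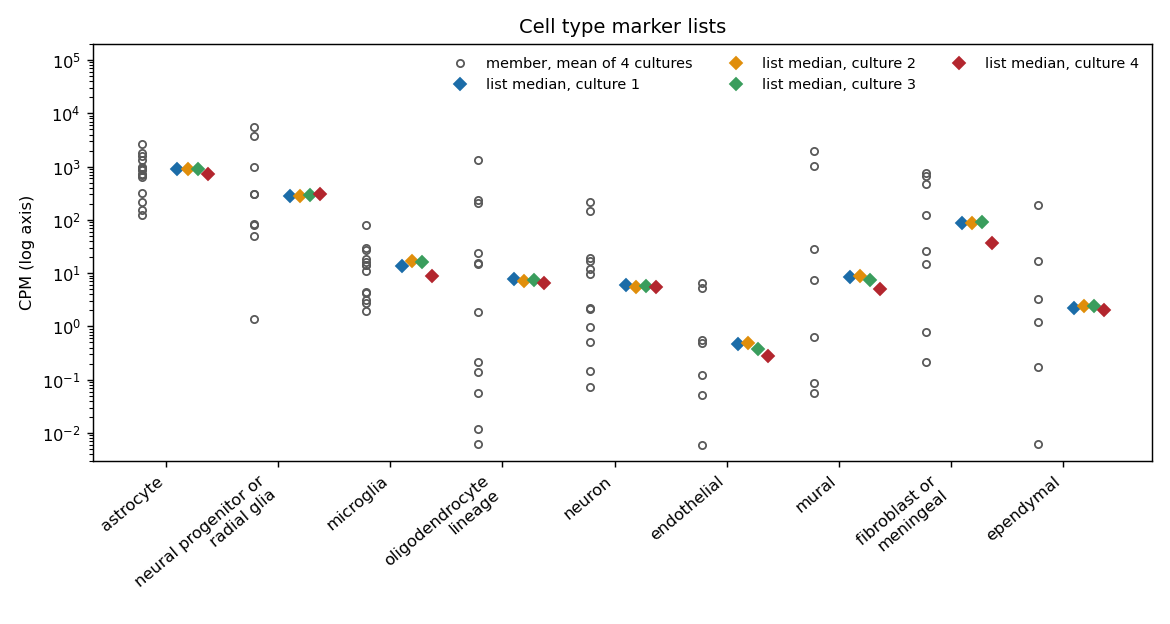
CPM on a log axis of the members of 9 cell type lists (open circles, mean of 4 cultures) and the list median in each culture (diamonds). The median of the astrocyte list was 886.4, 903.3, 903.6 and 726.9 CPM in cultures 1 to 4, and that of the fibroblast or meningeal list 87.3, 87.7, 91.8 and 36.5 CPM.

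The median of a list, averaged over the 4 cultures, was 855 ± 85.8 CPM for astrocytes, 288.1 ± 8.9 CPM for progenitors, 75.8 ± 26.3 CPM for fibroblasts or meningeal cells, 13.9 ± 3.58 CPM for microglia (12 of 13 expressed), 7.47 ± 1.71 CPM for mural cells (4 of 7), 7.16 ± 0.44 CPM for the oligodendrocyte lineage (7 of 12), 5.66 ± 0.20 CPM for neurons (8 of 12), 2.27 ± 0.18 CPM for ependymal cells (4 of 6) and 0.41 ± 0.10 CPM for endothelial cells (2 of 7). The microglial genes Csf1r and C1qa had 30.3 ± 4.62 and 26.6 ± 6.82 CPM, and 12 of the 13 microglial genes were lower in culture 4 than in the mean of the other cultures. Of the oligodendrocyte lineage, Olig1 (1310 ± 71.0 CPM), Olig2 (240.9 ± 7.89 CPM) and Cnp (207.6 ± 15.1 CPM) were high, while Sox10 had 0.06 ± 0.05 CPM and Mbp 1.88 ± 0.27 CPM. Of the neuronal list, Map2 had 214.0 ± 9.16, Stmn2 147.8 ± 4.73 and Gad1 18.9 ± 1.24 CPM, against 0.07 ± 0.08 CPM for Rbfox3 and 0.51 ± 0.13 CPM for Snap25. Of the mural list, the contractile genes Acta2 and Tagln had 1929 ± 53.3 and 1019 ± 98.2 CPM and Pdgfrb 28.5 ± 5.07 CPM. The highest endothelial genes were Kdr (6.48 ± 0.60 CPM), Flt1 (5.16 ± 2.43 CPM) and Esam (0.56 ± 0.21 CPM), and the highest ependymal genes Foxj1 (189.1 ± 9.34 CPM), Rarres2 (17.3 ± 3.91 CPM) and Cfap126 (3.34 ± 0.31 CPM). Of the fibroblast list, Fn1 had 766.9 ± 60.5 CPM, Col1a2 651.7 ± 161 CPM and Col1a1 464.9 ± 263 CPM, against 0.79 ± 0.22 CPM for decorin (Dcn) and 0.22 ± 0.15 CPM for lumican (Lum).

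Of the state lists, all 10 proliferation genes were expressed, with a list median of 165.8 ± 38.0 CPM, 142.4 to 154.5 CPM in cultures 1 to 3 and 222.2 CPM in culture 4. Cdk1 had 214.3 ± 24.5 CPM. All 12 reactive astrocyte genes were expressed at a median of 28.8 ± 7.96 CPM, with Cd44 at 287.1 ± 47.5, Emp1 at 142.6 ± 9.89 and Serpina3n at 103.3 ± 39.8 CPM. The 10 immediate early genes had a median of 15.8 ± 1.69 CPM, with Jun at 157.6 ± 14.3, Junb at 53.6 ± 12.8 and Egr1 at 40.8 ± 8.13 CPM, and 9 of the 10 were lower in culture 4 than in the mean of the others. The 8 ER stress genes had a median of 31.1 ± 2.11 CPM, with Hyou1 at 156.4 ± 8.17, Atf4 at 65.3 ± 2.34 and Xbp1 at 43.4 ± 2.65 CPM. The most abundant genes of the whole table were Pea15a (8398 ± 293 CPM), a phosphoprotein of astrocytes, Vim, the secreted binding proteins Igfbp2 (5486 ± 399 CPM) and Igfbp3 (4236 ± 484 CPM), Eef1a1 (3934 ± 195 CPM), Fabp7, creatine kinase B (Ckb, 3357 ± 195 CPM), Tmsb4x (3185 ± 179 CPM), Scd2 (2926 ± 117 CPM) and Actb (2907 ± 109 CPM). The 10 most abundant genes of each library, taken library by library, held 4.18 to 4.50% of that library's counts.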

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

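A result is given here when 1 culture lay far from the other 3, with a gap to its nearest neighbour, as a share of the whole range, beyond the critical value of Dixon's test for 4 samples. This was so for 50 of 210 values, with culture 4 the one apart in 45 of them, culture 1 in 1, culture 2 in 2 and culture 3 in 2. Chance gives about 1 in 20, which does not apply to genes chosen for a large spread or to sex-linked genes. Without these, it was so for 33 of 191 values against 9.6 by chance, 28 of them for culture 4, and values of 1 library are not independent of each other. Over all 14725 expressed genes, 2232 (15.2%) met the same criterion, 2032 of them for culture 4. The tests on split reads, on the share of astrocytes, on fibroblasts and on pups of both sexes were chosen after the results were seen.

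Among core calcium genes, culture 4 was the lowest for Stim2 (31.3 CPM against 38.9 to 39.7), Atp2b2 (5.81 against 10.1 to 10.9), Atp2b4 (144.6 against 193.6 to 200.6) and Slc8a1 (35.1 against 47.1 to 49.5). Other calcium genes lowest there were Saraf (164.5 CPM), Adora1 (136.0), Adora2b (1.37), Gjb6 (1.09), Nfatc4 (1.251) and S100a6 (34.5). Piezo1 (133.8 CPM) and Panx1 (12.8) were highest there. Ppp3cb was lowest in culture 3 (99.3 CPM against 108.6 to 109.1).

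Cell type and state genes lowest in culture 4 were Vim (4717 CPM), C1qa (16.5), Flt1 (1.53), Pdgfrb (20.9), Col1a2 (410.3), Col1a1 (72.4), Cd44 (216.1) and Serpina3n (43.7). Highest there were Top2a (663.3 CPM), Mki67 (405.6) and Cdk1 (250.6). Xist had 732.1 CPM in culture 4, and Eif2s3y (0.0708) and Ddx3y (0.0944) were lowest there. By list, the median CPM of culture 4 was the lowest for astrocyte (726.9), fibroblast or meningeal (36.5), reactive astrocyte (16.9) and sex-linked genes (0.0708), and the highest for proliferation (222.2).

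Of the abundant and variable genes, Igfbp3 (3515 CPM), Eef1a2 (1.79 against 49.2 to 54.1), Ucp2 (20.3 against 147.4 to 163.8), Gm5611 (2.21), Col6a2 (11.3) and Gpr37l1 (20.98 against 112.6 to 116.7) were lowest in culture 4. Eef1a1 (4225 CPM), Rps2-ps13 (107.0 against 7.44 to 8.51) and the imprinted gene Nnat (82.2 against 13.8 to 14.7) were highest there. Among log2 ratios of paralogues, culture 4 was the highest for Itpr1 over Itpr2 (0.97), Adora1 over Adora2b (4.98), Adra1d over Adra1b (1.42) and Plcg1 over Plcg2 (3.72), and the lowest for Atp2b4 over Atp2b1 (0.26). Culture 1 was the highest for Orai1 over Orai3 (0.13), culture 2 the highest for Htr2a over Htr2b (6.23) and the lowest for Lpar6 over Lpar4 (0.58), and culture 3 the lowest for Panx1 over Panx2 (4.72).

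The first pattern is that culture 4 lies apart from cultures 1 to 3. The mean chi-square per degree of freedom of pairs with culture 4 was 15.2 times that of the other pairs, and this ratio stayed at 14.4 with libraries thinned to the smallest total, 13.7 without the 100 most abundant genes, 14.4 without X and Y genes and 12.6 among genes with no split reads, so that library size, a few genes, the sex chromosomes or shared reads alone do not account for it. Taking out trends with GC content or exon length left 99.6% and 99.8% of the spread of its log2 deviations. A lower share of astrocytes that raised every other cell type would raise the microglia, mural and fibroblast lists. The lowest median deviation among these was -1.15. A lower share with a rise of only some cell types could not be tested this way and stays open. In culture 4 the median log2 deviation was -0.0951 for the astrocyte list (10 of 15 genes lower) and 0.0805 for the progenitor list (7 of 9 higher). Single genes ranged from -0.967 to 0.307 in the astrocyte list and from -0.317 to 0.534 in the progenitor list. By the sex-linked transcripts described below, culture 4 came from other animals, but whether this accounts for the differences in autosomal genes cannot be told apart from a difference in preparation: 5 genes that escape X inactivation lay at the 99.99th percentile of random lists of X-linked genes, a result that Xist had already fixed and that says nothing about other genes. The design names no biological difference between the cultures, so none from the design was tested, and sex, genotype and preparation stay open.

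The second pattern is the lower fibroblast list in culture 4, where 5 of the 6 members with a mean CPM of at least 1 were lower and Pdgfra was higher. The median log2 deviation of the list, -1.15, kept 101% of its size after the trend with GC content was taken out and 104% after that with exon length, so neither bias accounts for it. Fewer fibroblasts could not be tested, because Dcn, abundant in many fibroblasts, reached no more than 0.974 CPM in any of cultures 1 to 3. Whether other cells or a lower collagen expression in the same cells lie behind it cannot be told apart from these values.

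The third pattern is the split of sex-linked genes. If each culture had pooled pups of both sexes, every culture would hold both Xist and Y-linked transcripts, but in each culture 1 of the kinds was at most 0.101% of its highest level. The cells of each culture were therefore nearly all of one chromosomal kind by these transcripts, with Y-linked transcripts in cultures 1 to 3 and Xist in culture 4, so that culture 4 did not come from the same animals as cultures 1 to 3. The labels give no sex to compare this with.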

How the results depend on the processing

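The alternatives with cultures 1 to 3 summed and with GENCODE lengths were chosen after seeing the data. Across all settings, the count of expressed calcium genes was 152 to 267 (main 189; 189 to 195 without 1 culture), pairs past the threshold 383 to 444 (main 396; 390 to 414 without 1 culture) and families with a leading member 46 to 53 (main 48; 47 to 50 without 1 culture). The number of pairs tested differed between settings. The 383 pairs were of 422 and the 444 of 489, 90.8% in both, against 94.3% of 420 in the main setting. DESeq2 and limma with a pseudocount of 5 gave 396 pairs and limma with 0.5 gave 395. Without the library term, 395 of 420 pairs passed. Under TMM and DESeq2 size factors the mean CPM of the named genes moved by less than 1 SD. Leaving out 1 of 4 cultures can move a mean by at most 0.5 SD, so that criterion says nothing there: without culture 4, the Xist mean CPM went from 183.1 to 0.148 and the Col1a1 mean CPM from 464.9 to 595.8. Without the length term, 379 of the 396 calls were kept and 11 reversed, and with GENCODE lengths 380 and 9. Log2 ratios that reversed without the length term were P2rx4 over P2rx7 (-0.43), Gria3 over Gria2 (-1.28), Gna11 over Gnaq (-0.31), Calm2 over Calm3 (-0.82), Camk2g over Camk2d (-0.85) and Nfatc3 over Nfat5 (-0.31). With GENCODE lengths they were P2rx4 over P2rx7 (-0.13), Gria3 over Gria2 (-0.056), Lpar6 over Lpar4 (-0.34) and Camk2g over Camk2d (-0.63). The reversed ratios of P2rx4 and Gria3 with GENCODE lengths did not pass the threshold (edgeR, adjusted p = 0.214 and 0.333). The lengths of the paralogues are the only input that these settings change. Without single cultures, Calm2 over Calm3 ran from -0.032 (without culture 4) to 0.094 (without culture 3).

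The common BCV was 2.62 to 12.7% without 1 culture, with 2.62% without culture 4, and 17.1% with cultures 1 to 3 summed. The percentile of the calcium genes' spread was 61.8 to 99.8 without 1 culture, the lowest without culture 4. The medians that follow are taken over the mean levels of a list's genes, and not the mean of the 4 library medians. In TPM this median was 573.2 for astrocytes, 82.5 for progenitors, 9.87 for microglia, 2.40 for the oligodendrocyte lineage, 3.17 for neurons, 0.376 for endothelial, 4.20 for mural and 45.3 for fibroblast or meningeal cells, since the lengths enter and the unit differs. Without 1 culture, the median CPM was 284.1 to 301.4 for progenitors (299.3 with all 4), 7.34 to 8.57 for the oligodendrocyte lineage (8.26) and 5.72 to 6.13 for neurons (5.97), each lowest without culture 4. The neuronal median was 6.45 with cultures 1 to 3 summed. The cause of these last shifts was not tested.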

Other observations

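The lists of this part were chosen after the data had been looked at, while the tests of hypoxia genes and of neighbouring genes were written before their values were seen. Levels of channels and transporters of glial ion and transmitter handling ranged widely. The potassium channel Kcnj10 (Kir4.1) had 1684 ± 64.6 CPM (SD, n = 4), the pump subunit Atp1b2 1314 ± 304 CPM and the GABA transporter Slc6a11 83.3 ± 4.87 CPM. Kcnk1 had 39.1 ± 8.31 CPM, Slc7a11 23.9 ± 1.70 CPM and Kcnj16, a partner of Kcnj10, 3.27 ± 2.44 CPM, and all 12 genes of this list had a mean CPM of at least 1. In culture 4, 8 of the 12 were lower than in the mean of the other cultures, with Atp1b2 at 858.6 CPM against 1437 to 1491 CPM and Slc38a3 at 219.9 against 298.8 to 308.9 CPM, and Kcnj16 was higher at 6.89 against 1.56 to 2.34 CPM. The median log2 deviation of the list in culture 4 was -0.17, at the 0.52th percentile of 10000 random lists of the same size and expression, and the percentiles in cultures 1, 2 and 3 were 99.99, 93.31 and 86.97. Culture 4 is part of the mean set against each of cultures 1, 2 and 3, which raises their values for this list.

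Transcripts of GABA-A receptor subunits were present for 7 of 10 genes at a mean CPM of at least 1. Gabrb1 had 45.0 ± 5.53 CPM, Gabra4 23.1 ± 1.61 CPM, Gabrg1 14.9 ± 0.80 CPM and Gabra2 9.25 ± 3.61 CPM. Gabra2 stood at 3.87 CPM in culture 4 and at 10.5 to 11.4 CPM in the others.

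The lactate exporter Slc16a3, a known target of hypoxia signalling, was lowest in culture 1, at 2.41 CPM against 10.0, 8.90 and 24.4 CPM in cultures 2, 3 and 4. A lower hypoxia response in culture 1 was a candidate explanation, tested on 19 other hypoxia response genes. All 17 of them with a mean CPM of at least 1 were lower in culture 1 than in the mean of the other cultures, with a median log2 deviation of -0.24, and the percentile among 10000 random lists of the same size and expression was 0. It was 99.99 in culture 2, 84.52 in culture 3 and 99.96 in culture 4, where the median was 0.22. Culture 1 is part of the mean set against each of these cultures, which raises their values. Vegfa stood at 149.6 CPM in culture 1 and at 229.4, 210.5 and 244.9 CPM in cultures 2, 3 and 4, Pdk1 at 32.4 against 53.2, 51.6 and 65.8 CPM, Ero1a at 29.4 against 51.1, 48.5 and 59.1 CPM and Ldha at 679.2 against 824.0, 802.6 and 894.7 CPM. Compared one by one, culture 1 was below culture 2 in 17 of the 17 genes, below culture 3 in 16 and below culture 4 in 14. A lower hypoxia response in culture 1 is therefore a hypothesis. The genes of such a list move together, so the percentile describes 1 library and is no p-value. The labels give the same seeding of 200000 cells per dish for all 4 cultures, and nothing on cell density at RNA collection or on oxygen.

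A further hypothesis was that differences of genome segments between outbred animals may account for the genes over 2-fold apart in culture 4, which would then lie in clusters. Among 5413 autosomal genes with whole counts and a mean CPM of at least 5, 69 were more than 2-fold apart, and 3 pairs of them lay within 5 genes of this set of each other, against a mean of 4.17 in 10000 random draws (permutation test, one-sided, p = 0.804). No clustering was seen among these 69 genes. Genes with split counts were left out, and the number of pairs that segments would give is not known. The test therefore cannot decide on differences of genome segments, large or small.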
